A study of Mus musculus with 3 samples.

How the data were processed

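Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with a goat antibody against SOX2, a high-mobility-group transcription factor expressed in the stomach epithelium. Per the labels' protocols, the material was glands isolated from the mouse antrum, the distal part of the stomach. Formaldehyde at 1% was applied as the cross-linker, over 10 min, the chromatin was sheared by sonication, and 4 µg of antibody was used. Mice carrying loxP-flanked Sox2 alleles with a tamoxifen-inducible Cre recombinase at the Rosa26 locus formed the Sox2 knockout, and mice with the flanked alleles and no Cre formed the wild type. Both received tamoxifen at 8 weeks of age, and stomachs were taken 2 weeks later. The series holds 1 SOX2 ChIP library per genotype and 1 wild-type input library. A peak list was analysed for each ChIP library. The input was not analysed here.

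Reads were processed with Bowtie2 and MACS on the mouse build mm9, per the submitters' processing notes. Versions, settings and the control library used in peak calling are not given in the sources used here. The deposited files hold, for each peak, its position and a score given by the authors' peak caller. The lowest score was 50 in the wild-type list and 50.02 in the knockout list. Such a floor is common for a peak score computed from a p-value, but no source names the scale, so the values are treated as a score that ranks peaks. Peaks were called for each library separately, as the authors deposited 1 list per sample. The read depth behind each list is unknown, and a score and a number of peaks both move with depth. Scores of different libraries are therefore given side by side and not tested. A score is the authors' value for a peak and is used to describe, rank and filter peaks within a list.

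With 1 library per genotype no test between genotypes was possible, and no p-value was computed. Overlap was at least 1 bp (bedtools 2.31.1). Shares of peaks have exact Clopper-Pearson 95% intervals, and medians over peaks have exact binomial order-statistic 95% intervals. A share of 0 is given with the limit of 3 counts over the total in place of an interval. These limits and intervals cover counting error only, since peaks are not replicates. Overlap was set beside 1000 random placements of the knockout peaks on their own chromosomes, within the span from the first to the last peak of either list. The spacing of wild-type-only peaks was set beside 1000 placements of those peaks made in the same way. Chromosome densities are peaks per Mb of that span, with exact Poisson 95% intervals, because the lists give no chromosome lengths. Each knockout peak was paired with the wild-type peak it overlapped by the most bases. The scores of a pair were set side by side and compared by rank. After the lists had been seen, regions holding overlapping peaks of at least 1 kb in both lists were marked, with 50 kb added on each side. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

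The overlap count was tested on simulated data, with 3 simulated knockout lists against random lists of 7213 wild-type peaks. All 1331 planted overlaps were found, 7 of 1330 unplanted peaks also overlapped, and no peak was counted differently by bedtools. Each planted peak was a wild-type peak shifted by less than its own width, so an overlap of 1 bp was certain. The simulation therefore checks the counting only.

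The rule for named peaks was fixed before the data were examined. It takes the 10 wild-type-only peaks, the 5 shared wild-type peaks and the 5 knockout-only peaks with the highest scores, by position where no annotation of the build is at hand. A genome and gene annotation of mm9 were not used here, and the gene table at hand was on another build. Peaks were therefore not assigned to genes, and Sox2 itself has no value here. The planned shares of peaks in promoters, gene lists near peaks and SOX motifs in peaks were not computed. Alternatives were the score limit, the chromosomes and peak widths kept, and the overlap rule. Positions are given 1-based on mm9.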

Results

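SOX2 binding was measured by ChIP-seq in antral gastric glands of Sox2 wild-type mice and of mice in which Sox2 had been deleted by tamoxifen-induced recombination. The study was designed to find SOX2 targets in the stomach, and the knockout shows which peaks were still called with the same antibody after deletion. There was 1 ChIP library per genotype, without replicates. The wild-type list held 7213 peaks and the knockout list 887. Read depths were unknown.

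Antral glands of the wild type held 8.13 times as many SOX2 ChIP peaks as those of the knockout. Wild-type peaks covered 2502 kb and knockout peaks covered 266 kb. The median score was 82.62 (95% interval 81.08 to 84.34) in the wild-type list and 63.15 (61.93 to 64.11) in the knockout list. The median width was 320 bp (317 to 323) in the wild type and 235 bp (229 to 241) in the knockout. A score of at least 100 was given to 2802 wild-type and 137 knockout peaks, a ratio of 20.5. The strongest wild-type peak scored 2097.47 and the strongest knockout peak 580.08, and they overlapped on chromosome 2. Unequal depth of the libraries would also change these numbers, and no replicate error is available for them.

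Of the wild-type peaks, 6625 (91.8%, exact interval 91.2 to 92.5) did not overlap a knockout peak. Their median score was 78.52, and the knockout list holds no score under 50.02. A site with weaker knockout signal would not be listed, so a missing knockout peak does not show that signal was absent. The strongest wild-type-only peak lay on chromosome 16 from 52438212 to 52438719 and scored 811.47. The nearest knockout peak was 251 kb away. The next were on chromosome 12 from 31941298 to 31941857 with a score of 723.22 and on chromosome 11 from 63337662 to 63338396 with a score of 722.26. Chromosome 13 held a pair of them, from 102606609 to 102607199 with a score of 679.05 and from 114143689 to 114144573 with a score of 649.54. The peak on chromosome 2 from 157585358 to 157585892 scored 596.95, that on chromosome 1 from 36976820 to 36977542 scored 584.57, and that on chromosome 18 from 65230718 to 65231606 scored 574.85. The last of the 10 were on chromosome 1 from 135968096 to 135968703, with a score of 543.04, and on chromosome 17 from 43305146 to 43305695, with a score of 537.03. The peak on chromosome 17 had a knockout peak 6.53 kb away, while the nearest to the one on chromosome 1 at 36976820 was 15076 kb away.

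Most of the 100 highest-scoring wild-type peaks overlapped a peak of the knockout list. All of the 10 highest-scoring wild-type peaks and 92 of the top 100 overlapped a knockout peak. Across the whole list the number was 588 of 7213, or 8.15% (exact interval 7.53 to 8.81). The share was 45.0% (41.3 to 48.7) among the 10% of wild-type peaks with the highest scores, 14.6% (12.1 to 17.4) among the 10% ranked below them and 1.25% (0.572 to 2.35) among the 10% with the lowest scores. Wild-type peaks with a knockout peak had a median score of 246.02 (227.97 to 264), and those without had a median of 78.52 (77.04 to 80.47). From the knockout side, 592 of 887 peaks (66.7%, 63.5 to 69.8) overlapped a wild-type peak. Placement of the knockout peaks at uniformly random positions gave a median of 3 such peaks and at most 8 in 1000 placements.

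**Figure D1:**
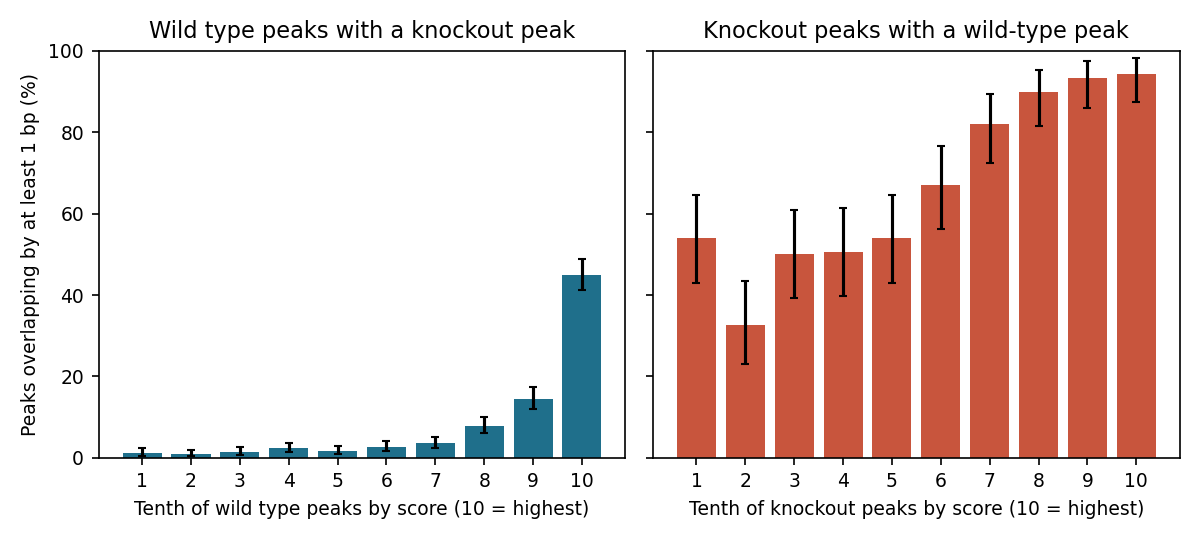
Share of peaks overlapping a peak of the other genotype by at least 1 bp (%). Peaks of each list were ranked by score and split into 10 bins of nearly equal peak number. Bars are shares and error bars exact 95% binomial intervals. The share of wild-type peaks with a knockout peak goes from 1.25% in the lowest bin to 45.0% in the highest.

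Each shared peak has a score in both lists, which ranks it within that list. The highest-scoring shared peak was on chromosome 2 from 25035923 to 25036494, with a score of 2097.47 in the wild type and 580.08 in the knockout. On chromosome 17 from 15345031 to 15345512 the scores were 1427.13 and 282.13. On chromosome 19 from 10760115 to 10760810 they were 1314.85 and 419.45. On chromosome 1 from 140244890 to 140245601 they were 1285.76 and 182.53, and on chromosome 7 from 147307294 to 147307968 they were 1267.21 and 230.93. Over the 592 pairs of overlapping peaks, the median score was 246.3 in the wild-type list and 71.19 in the knockout list. A site under the lowest knockout score makes no pair. Across peaks, which are not independent replicates, the ranks of the pairs in the lists had a Spearman rho of 0.46.

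**Figure D2:**
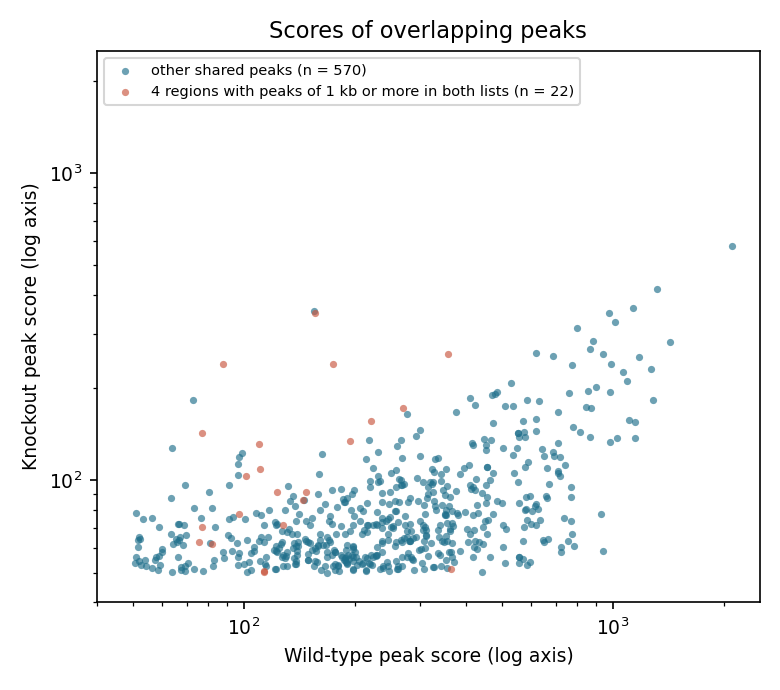
Knockout against wild-type peak score of overlapping peaks, both on log axes; each point is a knockout peak paired with the wild-type peak it overlaps most. Knockout scores of the 592 pairs begin at the lowest score of that list, 50.02, and reach 580.08 at the pair with the highest wild-type score, 2097.47.

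**Figure D3:**
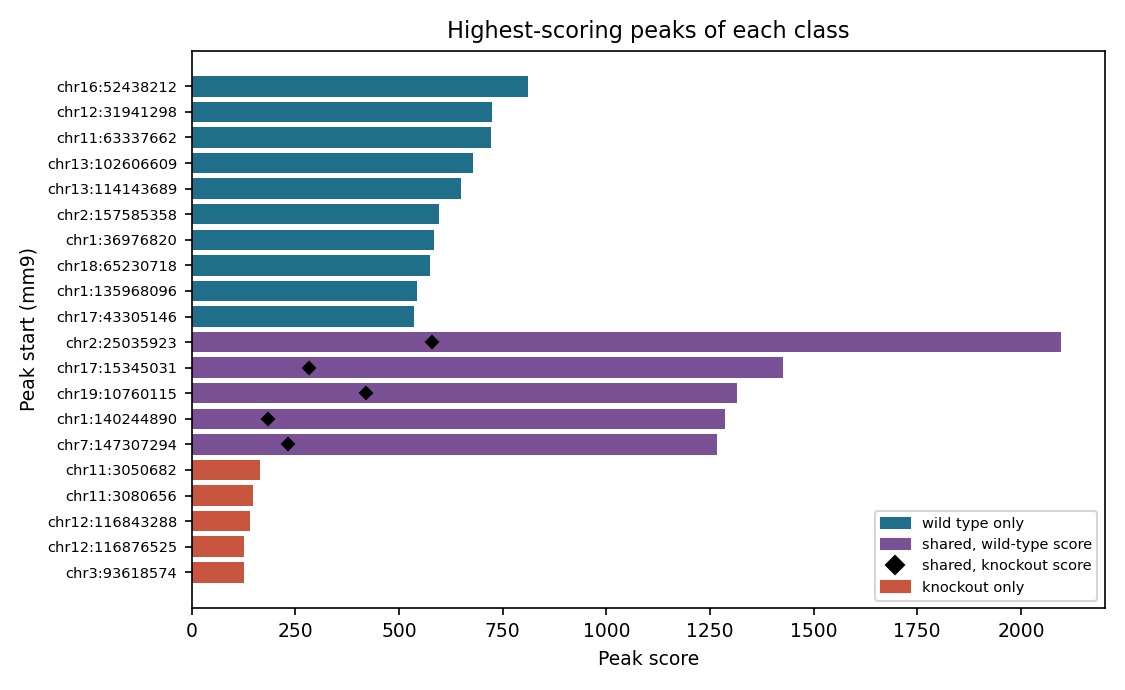
Peak scores of the 10 highest wild-type-only, 5 highest shared and 5 highest knockout-only peaks, labelled by mm9 start; bars are scores and diamonds the knockout score of shared peaks. In the wild-type list the shared peaks reach from 1267.21 to 2097.47, above the wild-type-only peaks at 537.03 to 811.47, and the knockout-only peaks have knockout scores of 125.03 to 164.24.

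Of the knockout peaks, 295 (33.3%, 30.2 to 36.5) did not overlap a wild-type peak. They ranked low in their list, with a median score of 56.66 (55.5 to 57.65) against 71.19 (68.26 to 72.83) for the overlapping knockout peaks, and a median width of 210 bp (208 to 214), and 10 had a score of at least 100. The first of them lay on chromosome 11 from 3050682 to 3051631 with a score of 164.24, followed by the peak from 3080656 to 3083072 with a score of 147.44. Both were inside a stretch of wide peaks in both genotypes. Chromosome 12 held the next peaks, from 116843288 to 116843643 with a score of 140.96 and from 116876525 to 116876942 with a score of 126.77. The former was 0.358 kb from a wild-type peak. The fifth was on chromosome 3 from 93618574 to 93618877, with a score of 125.03 and the nearest wild-type peak 308 kb away.

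The lists held 4 regions where both genotypes had overlapping peaks of at least 1 kb. On chromosome 11 from 3023738 to 3100150 there were 9 wild-type and 13 knockout peaks, covering 32510 bp and 28871 bp, and the highest score was 351.04 in the knockout against 174.66 in the wild type. On chromosome 9 from 2999989 to 3038425 there were 15 wild-type peaks with a highest score of 363.86 and 12 knockout peaks with a highest score of 155.51. On chromosome 2 from 98502367 to 98507509 each genotype had 3 peaks. The remaining region was on an unplaced contig, with 2 wild-type peaks and 1 knockout peak. Over the 22 pairs in these regions, the median score was 118.1 in the wild-type list and 97.4 in the knockout list. Over the 570 pairs elsewhere, the medians were 253.5 and 70.3. Because the knockout list has a lowest score, pairs with lower wild-type scores lie closer together in part by construction. Without these regions, 7184 wild-type and 858 knockout peaks were left, and 7.91% of the wild-type peaks (7.29 to 8.55) overlapped a knockout peak.

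Wild-type peaks were spread over all 19 autosomes and were sparse on chromosome X. The autosomal median was 2.96 peaks per Mb, with the lowest density on chromosome 1 at 2.42 (2.20 to 2.65) and the highest on chromosome 19 at 4.46 (3.93 to 5.04). Chromosome 11 had 4.22 peaks per Mb (3.86 to 4.61). Chromosome X held 57 wild-type peaks, or 0.358 per Mb (0.271 to 0.463), and 3 knockout peaks. None of the 57 overlapped a knockout peak, which allows a share of up to 5.26% by the limit of 3 counts. Knockout peaks had an autosomal median of 0.354 per Mb.

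**Figure D4:**
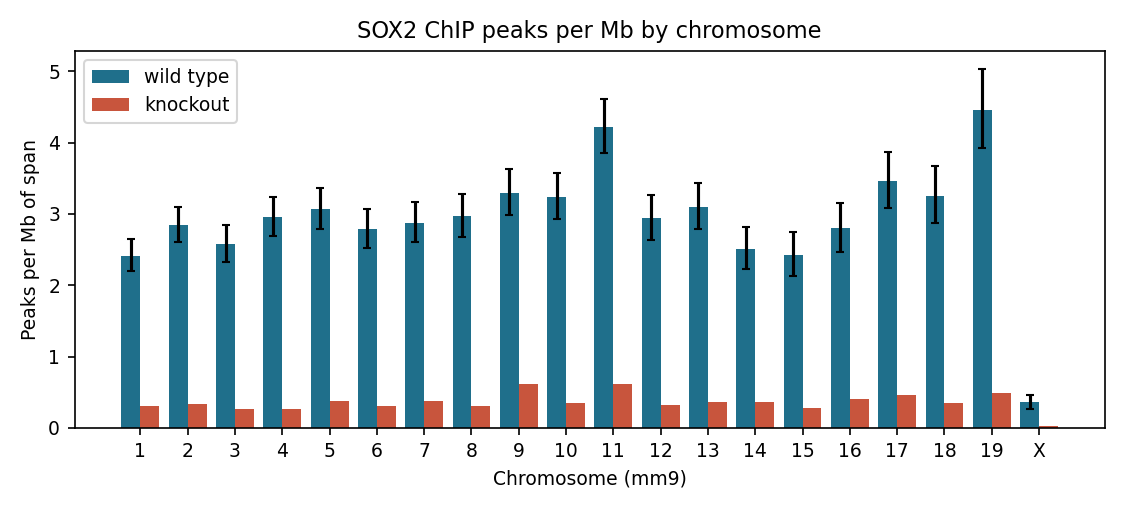
SOX2 ChIP peaks per Mb of the span between the first and last peak of each mm9 chromosome, for the wild type and the knockout; bars are densities and error bars on the wild-type bars are exact 95% Poisson intervals. Chromosome X has 0.358 wild-type peaks per Mb, compared with 2.42 to 4.46 on the autosomes.

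Wild-type-only peaks lay closer together than randomly placed ones. Outside the regions of wide peaks, 640 neighbouring pairs among 6616 peaks were less than 5 kb apart. Random placements gave a median of 97 and at most 134. The placements took every position of a span as equally likely. Spacing of shared or knockout peaks was not examined, so closeness is not shown to be particular to wild-type-only peaks. Joining peaks up to 12 kb apart gave 9 clusters of 5 or more peaks, and no placement gave more than 1. The largest had 7 peaks on chromosome 12 from 116837046 to 116859646, where the knockout also had peaks. Shared peaks between them scored 217.75, 98.73, 83.26, 97.17, 275.88 and 155.23 in the wild-type list. Their knockout partners scored, in that order, 135.29, 122.39, 70.29, 118.61, 164.64 and 355.37. The knockout-only peak with a score of 140.96 lay there too. Clusters of 6 lay on chromosome 3 from 15098229 to 15123836 with a highest score of 265.13, on chromosome 6 from 99103775 to 99123832 with 237.5, and on chromosome 4 from 9588460 to 9614002 with 143.83. On chromosome 11, a cluster of 5 from 112898963 to 112914269 held a peak with a score of 407.3. The cluster counts were chosen after the lists had been seen.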

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

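Of 45 alternatives over 12 reported values, 29 left the value within its counting interval, or a count within 1.5 times, and 16 moved it. The wild type had more peaks than the knockout under each score, chromosome and width setting run, and wild-type peaks with a knockout peak had the higher median score under each overlap setting run. A score of at least 100 left 2802 wild-type and 137 knockout peaks, a ratio of 20.5. The upper 50% of the pooled scores left 3812 and 239, a ratio of 15.9. The share of wild-type peaks with a knockout peak was 5.75% with a reciprocal overlap of at least 50%, 18.3% among wild-type peaks with a score of at least 100 and 40.1% among as many top wild-type peaks as there were knockout peaks. The share of knockout peaks with a wild-type peak was 46.8%, 58.2% and 40.6% under the same settings. In the filtered settings the wild-type share rose because shared peaks score higher, and the knockout share fell because wild-type peaks were removed. The median score of wild-type peaks with a knockout peak was 217.75 with the reciprocal overlap, and the cause was not tested. Of the 5 named knockout-only peaks, 3 had no wild-type peak within 1 kb, while the 10 named wild-type-only and 5 named shared peaks kept their class. A peak without overlap cannot change class under the reciprocal rule, nor can a shared peak under the 1 kb rule. These outcomes were fixed in advance, though they count among the 29. Neighbours closer than 5 kb numbered 98 among the 2288 wild-type-only peaks with a score of at least 100. Among all 6616, 966 were closer than 10 kb. No placements were run for these settings, so neither number can be set beside the random counts given above. The settings without the regions of wide peaks, and those for the knockout share, chromosome X, spacing and named peaks, were chosen after the data were seen. Alternatives listed beforehand for promoters, gene lists and motifs were not run, because no annotation or genome of the build was used here. No replicate could be left out, and unknown depth limits every comparison of numbers and scores between the genotypes.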

Other observations

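All tests in this part were chosen after the results had been seen. The knockout list held 92 of the 100 highest-scoring wild-type sites, and 53.8% of the top 500. Coincidence of uniformly random positions is argued against, since no random placement gave more than 8 overlapping knockout peaks, compared with 592 observed. The placements took every position of a span as equally likely. They do not address overlap at sites where a peak of any list is more likely. A candidate explanation is that the knockout library carried a fraction of the wild-type signal, from cells that kept SOX2 after tamoxifen or from carry-over between libraries. Outside the regions of wide peaks, 44.8% (41.1 to 48.5) of the peaks in the top 10% by score had a knockout peak, against 1.47% (1.11 to 1.92) of those in the lower 50%. This gradient prompted the explanation and decides nothing, because lower depth and signal that does not need SOX2 predict it as well. A fraction of the wild-type signal and signal at the same sites that does not need SOX2, such as unspecific recovery of open chromatin, both stay open. The input was not analysed here.

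Outside the regions of wide peaks, 277 of 858 knockout peaks (32.3%, 29.2 to 35.5) had no wild-type peak within 1 kb. The median score of these 277 peaks was 56.28 (55.31 to 57.45), and 3 of them scored 100 or more.

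The smaller number of knockout peaks may come from lower sequencing depth alone. Wild-type peaks of at least 1 kb were set beside narrower peaks of matched score. The comparison assumed that a uniform loss of depth keeps both equally often. This may fail, because a wider peak offers more bases for an overlap of 1 bp. A knockout peak overlapped 15 of the 22 wild-type peaks of at least 1 kb (68.2%), and narrower peaks of matched score gave 14.8%. The 22 peaks lay in only 7 regions, however, and 5 of the 7 regions (71.4%, 29.0 to 96.3) had an overlap, against 41.4% predicted for the regions. Depth and genotype therefore cannot be told apart by this check, because the regions are few and wide peaks offer more bases to overlap. The loss of SOX2, which the design names, stays among the open explanations.

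Chromosome X had 12.1% of the autosomal median density of wild-type peaks, and 10.0% among peaks with a score of at least 100. A single X chromosome per cell might contribute, but the sex of the animals is not in the labels used here. If scores fell by 50%, 39.0% of autosomal peaks would still pass the lowest score, so the density on X was lower than this rough calculation gives. The calculation assumes that score scales with copy number and decides nothing.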
